A study of Canis lupus familiaris with 32 samples.

How the data were processed

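Expression arrays were analysed for 32 skin biopsies from 8 Maltese-beagle atopic dogs sensitized to the house dust mite, per the labels. Each dog gave a control biopsy 6 h after a mineral oil patch and biopsies 6 h, 24 h and 48 h after a mite patch on the lateral thorax. Total RNA was converted to cDNA and labelled with biotin, per the labels' protocols. The deposited table of array values holds log2 signals for 43035 probe sets on the 32 arrays, and each array is 1 biopsy. How the authors summarised and normalized these log2 values, the array design and the genome build are not given in the sources used here. The authors also deposited a gene table of 17107 genes with a signed fold and an adjusted p-value for 6 h, 24 h and 48 h against the control.

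The value table carries no gene names, so genes were named through the authors' gene table by equal values. An ordinary linear model without the dog was fitted to each probe set, and its 3 folds and 3 adjusted p-values were compared with each gene of the table. A gene was linked when its 6 values equalled those of exactly 1 probe set, within 0.05 for the fold and 0.001 for p. This held for 10526 genes, against 179 for limma without the dog and 8 for an ordinary model with the dog. In 4 cases 2 or more probe sets matched, and in 6577 cases none did. After 11 were dropped for a shared probe set, a name turned into a date or an array control, 10515 were used (61.5%). With the 24 h and 48 h values shuffled between genes of the table, 5 times over, 34 genes were linked on average and 42 at most, which gives about 13.1 wrong links among those used. The rule of representing a gene by its probe set with the highest mean was therefore replaced by the matched probe set, after the data were examined.

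The log2 values were used as deposited. In all, 175 array controls were left out and 42860 probe sets were tested, with no filter on dim ones. limma 3.58.1 in R 4.3.3 fitted the 4 groups to all 32 arrays with the dog as a fixed block, and 6 comparisons were read from this fit: each time against the control, and each pair of times. Tests are 2-sided moderated t tests with Benjamini-Hochberg adjustment over all tested probe sets, and a probe set passed at an adjusted p of 0.05. The pairing comes from the labels, which name the dog of each biopsy. It was checked by the correlation of deviations from the group means, which averaged 0.16 over 48 pairs of arrays of the same dog. These ranged from -0.46 to 0.70, with 33 above 0.1. The mean over arrays of different dogs and groups, -0.02, follows largely from subtracting the group means and is no separate benchmark. The fit had 21 residual degrees of freedom.

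Gene lists, 37 in number, were written with the design, comparisons, threshold and alternatives before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of list members past the test are given adjusted over all probe sets and over the list alone. Because the control arrays are shared by 3 comparisons, correlations between times were set against 20 simulations with no true change and against fits in which each time had its own 4 control dogs. Those fits took the allergen arrays from the same 4 dogs, so each rests on fewer arrays. Named genes follow a fixed rule. For each comparison with the control these are up to 8 rises and 8 falls, the largest among genes that passed and had the same sign in at least 7 of 8 dogs. For each comparison between times they are up to 4 rises and 4 falls. Genes fixed in advance for the question of the series, and up to 4 members per list, were added. Genes given with a value from the authors' deposited table alone have no linked probe set. CD247, STS and FPR2 at 48 h, CFD at 24 h, and SREBF2, TREM1 and LOX from 6 h to 24 h fall outside this rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

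Measures of whole arrays (median signal, mean of 8 linked muscle markers, and control probe sets) were compared with the control by exact permutation over sign changes within dogs, 256 in all. The same fit was tested on simulated data with 50 probe sets changed at each of 4 sizes in the 48 h comparison. It recovered 90% at 1.5-fold, 94% at 2-fold, 96% at 3-fold and 100% at 4-fold, and 12 unchanged probe sets were called, 5.94% of the calls. With nothing changed, 0 probe sets were called in limma over the 6 comparisons, and of 36 lists without a shift 0 passed in camera. The simulated noise was independent between probe sets and the lists were drawn at random. These simulations therefore do not test false calls from correlated genes or from differences between arrays such as muscle. Alternatives tried were fits without the dog or with it as a random effect, fits to 2 groups only, quantile normalization, centring on array medians, a filter on dim probe sets, an intensity trend with a robust prior, array weights, a fold of at least 1.5, and leaving out each dog. Further alternatives, chosen after the data were examined, were a muscle covariate, an actin covariate, leaving out arrays, and an ordinary linear model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.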

Results

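Skin gene expression was measured on arrays in 8 Maltese-beagle dogs, a colony with atopic dermatitis, that had been sensitized to the house dust mite Dermatophagoides farinae. Each dog gave 4 biopsies: skin 6 h after mineral oil alone, which is the control, and skin 6 h, 24 h and 48 h after the mite allergen. There are 32 arrays, 8 per group, and each dog is in each group. The median log2 signal of an array lay between 4.64 and 4.91, and the number of arrays limits the precision of every value. The control was taken at 6 h, so time since patching differs along with the allergen in the comparisons at 24 h and 48 h. Genes were named through the authors' gene table, which was joined to the probe sets by equal values. That join names 10515 of the table's 17107 genes, with about 13.1 wrong names expected among them, so counts over named genes cover 61.5% of that table. Means are given with their SD over 8 dogs on the log2 scale. Changes are log2 differences from the within-dog model, with SE and adjusted p.

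The biopsies differed in how much skeletal muscle RNA they held. The mean log2 signal of 8 muscle markers was 4.93 ± 1.74 in control skin, 6.22 ± 2.16 at 6 h, 4.12 ± 1.83 at 24 h and 3.12 ± 0.08 at 48 h (SD, 8 dogs each). The arrays split into 9 rich in muscle, at 6.95 or more, and 23 others, at 5.21 or less. Of the 9, 2 were control arrays, 5 were 6 h arrays and 2 were 24 h arrays. The first principal component, with 36.2% of the variance, placed these 9 arrays between 22.1 and 76.3 and the other 23 between -50.5 and 7.40. At 48 h the muscle signal was lower than in the control in 8 of 8 dogs, by 1.81 on average (exact permutation test over sign changes, 2-sided p = 0.0078, adjusted p = 0.070 over 18 tests). The beta-actin control, whose 3' minus 5' difference is larger when RNA is more degraded, read 2.27 ± 0.32 in control skin, 2.78 ± 0.48 at 6 h, 2.08 ± 0.37 at 24 h and 1.79 ± 0.29 at 48 h. It was higher at 6 h in 7 of 8 dogs (exact permutation p = 0.023) and higher at 48 h in 0 of 8 (exact permutation p = 0.0078), both with adjusted p = 0.070. The GAPDH control did not show a wider gap at 6 h. Its 5' signal was higher than in the control by 0.82 and its 3' signal by 0.47 (exact permutation, adjusted p = 0.42 for each). At 24 h these differences were 0.006 and 0.19, and at 48 h 0.16 and 0.23. The GAPDH 5' signal was 11.67 to 12.77 on the 9 muscle-rich arrays and 10.06 to 11.62 on the other 23. GAPDH thus moved with muscle, and its gap cannot decide on RNA integrity at 6 h. A reading of RNA integrity at 6 h therefore rests on actin alone. The bioB hybridization control was higher at 6 h in 7 of 8 dogs (by 0.24, exact permutation p = 0.016). Array medians were higher than in the control in 1 of 8 dogs at 24 h (difference -0.05, exact permutation p = 0.023) and in 1 of 8 at 48 h (difference -0.03, exact permutation p = 0.016), all with adjusted p = 0.070.

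**Figure D1:**
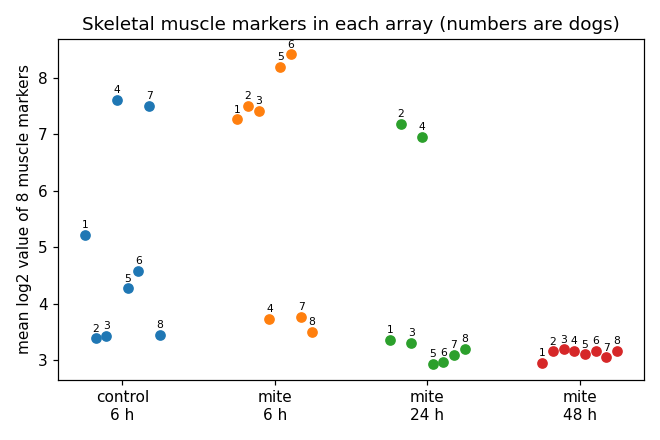
Mean log2 signal of 8 skeletal muscle markers on each array, by group, with each dog shown by its number. The 9 arrays at 6.95 or above stand apart from the other 23, and all 8 arrays of the 48 h group lie between 2.96 and 3.19.

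The comparison of 6 h allergen skin with 6 h control skin asks which transcripts respond first. Most that passed the test were lower than in the control. S100A12, an alarmin of neutrophils and activated keratinocytes, fell by 1.81 (SE 0.48, adjusted p = 0.0401), from 8.94 ± 1.32 to 7.12 ± 1.20, in 8 of 8 dogs. Its relative S100A8 fell by 1.20 (SE 0.33, adjusted p = 0.0446), from 10.57 ± 0.95 to 9.37 ± 0.61, in 7 of 8 dogs. CCL24, an eosinophil-attracting chemokine, rose by 0.98 (SE 0.23, adjusted p = 0.0200), from 5.92 ± 0.62 to 6.90 ± 0.70, in 8 of 8 dogs. CYP1A1, a target of the aryl hydrocarbon receptor, rose by 0.92 (SE 0.23, adjusted p = 0.0278), from 5.58 ± 0.44 to 6.50 ± 0.75, in 8 of 8 dogs.

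Genes of keratinocyte activation and wound response were the list with the clearest shift at 6 h. Of its 15 linked members 4 fell and none rose, or 7 adjusted over the list alone. The median change was -0.44 (camera, adjusted p = 0.000261; adjusted p = 0.609 with an estimated correlation). Among them are the matrix protease MMP3 (-0.99), the growth factor EREG (-0.73) and the integrin ITGA2 (-0.52), each lower in 8 of 8 dogs. Of 20 linked genes of the Th22 and Th17 axis 4 fell, or 5 adjusted over the list alone: S100A12, S100A8, the epithelial cytokine IL36G (-0.79) and its antagonist IL36RN (-0.65). Their list did not shift as a whole (mean change -0.26, median 0.00, adjusted p = 0.493). Of 13 linked junction genes 2 fell, also 2 adjusted over the list alone: CLDN1, a tight junction claudin (-0.64, adjusted p = 0.00652, 8 of 8 dogs), and CTNNB1, beta-catenin (-0.33, adjusted p = 0.0115, 7 of 8 dogs). Of 13 linked immediate early and heat shock genes 2 fell, or 4 adjusted over the list alone, the chaperones HSPH1 (-1.03) and HSPA8 (-0.47). The list median was -0.17 (adjusted p = 0.0368; adjusted p = 0.741 with an estimated correlation). Of 25 linked acute inflammatory genes 2 fell, or 5 adjusted over the list alone: the lymphocyte chemokine CCL19 (-0.84) and SOD2, a mitochondrial antioxidant enzyme (-0.69). The actin difference, higher in 7 of 8 dogs at 6 h, moved with these falls.

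Further falls at 6 h were ISG20, an interferon-induced exonuclease (-1.21), BCLAF1, a nuclear RNA-processing factor (-1.05), CLINT1, a clathrin adaptor (-1.03), and SLC12A2, a sodium, potassium and chloride cotransporter (-0.98), each in 8 of 8 dogs, with adjusted p from 0.00161 to 0.0177. Further rises were the stromal chemokine CXCL12 (0.63), DMXL2 (0.62), PGM2L1 (0.61), ANGPTL7 (0.55), MXRA8 (0.53) and CCDC28A (0.46), in 7 or 8 of 8 dogs. CCL24 was the 1 member of 22 linked Th2 genes that rose. IL13 differed by 0.72 (adjusted p = 0.202), IL5 by 0.33 (adjusted p = 0.107), IL4 by 0.28 (adjusted p = 0.303), CCL17 by 0.53 (adjusted p = 0.719) and IL33 by -0.22 (adjusted p = 0.724), and none passed the test. Of 24 linked itch mediators and receptors 0 passed in limma at 6 h (2 at an unadjusted p under 0.05), and the list median was -0.03 (adjusted p = 0.919).

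Over all 42860 probe sets, 118 rose and 1121 fell at 6 h, 4 and 12 of them at least 2-fold, and 6984 had an unadjusted p under 0.05. Among linked genes 34 rose and 429 fell. The authors' deposited table, from a model without the dog, lists 11 genes up and 240 down at its adjusted p. The total of 1239 was 469 without the dog as a block. This ended the calls of 17 of the 27 named genes, S100A12 (adjusted p = 0.124), S100A8 (adjusted p = 0.112), CCL24 (adjusted p = 0.177) and CYP1A1 (adjusted p = 0.206) among them. With the actin difference as a covariate it was 0 in limma (4007 at an unadjusted p under 0.05). Without the 9 muscle-rich arrays it was 0 in limma (1835), with 6 control and 3 allergen arrays left and both kept in dog 8 alone. It was 398 without dog 1, 586 without dog 2, 283 without dog 3, 1878 without dog 4, 624 without dog 6 and 583 without dog 8. It was 530 with the muscle score as a covariate, 2004 with array weights and 1915 without the 24 h array of dog 5.

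**Figure D2:**
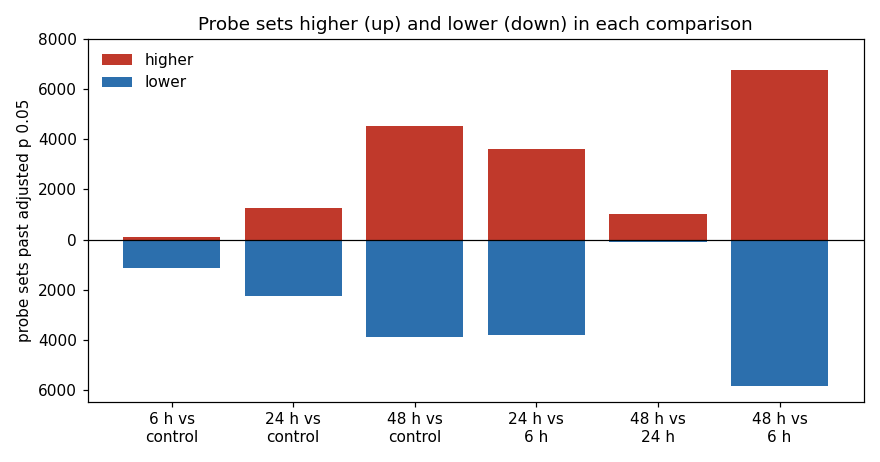
Number of probe sets past an adjusted p of 0.05 in each of the 6 comparisons, with rises above 0 and falls below 0. Falls outnumber rises at 6 h (1121 against 118), and the number past the test is larger at 48 h (8438) than at 6 h (1239).

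At 24 h the comparison with control skin asks which transcripts differ later after the allergen. CCL17, a chemokine that draws Th2 cells through CCR4, rose by 3.84 (SE 0.58, adjusted p = 0.000189), from 4.06 ± 0.19 to 7.90 ± 1.96, in 8 of 8 dogs. The control signals of CCL17, IL13, IL13RA2 and CD3D lie below the mean array median of 4.88, and no background level was available, so no fold is given for them. The signals of IL9 at 6 h (2.03 to 2.83), IL4 at 6 h (2.05 to 3.63) and IL5 at 24 h (2.47 to 3.14) also lay below it. The size of a log2 change from such dim signals is uncertain. The Th2 cytokine IL13 rose by 1.65 (SE 0.29, adjusted p = 0.000873), from 3.72 ± 0.18 to 5.36 ± 0.85, in 8 of 8 dogs. IL13RA2, the decoy receptor for IL13, rose by 2.58 (SE 0.35, adjusted p = 8.23e-05), from 4.32 ± 0.45 to 6.89 ± 1.34, in 7 of 8 dogs. S100A8, lower at 6 h, was higher than in the control at 24 h (1.13, SE 0.33, adjusted p = 0.0305, 7 of 8 dogs).

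Of 22 linked Th2 genes 9 rose and none fell, or 11 adjusted over the list alone. The median change was 0.31 (adjusted p = 3.13e-07; adjusted p = 0.0356 with an estimated correlation). IL9, a growth factor for mast cells, rose by 1.83, CCL24 by 1.83 and IL5, the eosinophil growth factor, by 0.45, each in 8 of 8 dogs. IL4 differed by 0.38 (adjusted p = 0.0807) and IL33, an epithelial alarmin, by 0.76 (adjusted p = 0.0517). Of 25 linked acute inflammatory genes 9 rose, or 12 adjusted over the list alone. The median was 0.45 (adjusted p = 1.32e-09; adjusted p = 0.129 with an estimated correlation). Among them SAA1, an acute phase protein, rose by 1.99 (SE 0.34, adjusted p = 0.000614) from 9.48 ± 0.40 to 11.47 ± 0.61, and TNFAIP6, a hyaluronan-binding protein induced by TNF, by 1.92. CCL5, a T cell chemokine, rose by 1.51 (adjusted p = 0.00738), and IL6 differed by 1.60 (adjusted p = 0.0724). The largest further rises were GSDMC, a gasdermin (2.02), NLRP10, a NOD-like receptor of epidermis (2.00), the interferon-induced chemokine CXCL10 (1.86) and BATF3, a transcription factor of cross-presenting dendritic cells (1.85). Of 15 linked dendritic and Langerhans cell markers 3 rose, or 6 adjusted over the list alone: BATF3, the tryptophan-degrading enzyme IDO1 (1.18) and the lectin CD209 (1.03) (list median 0.21, adjusted p = 4.07e-05; adjusted p = 0.213 with an estimated correlation).

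Smaller groups also shifted at 24 h. Of 8 linked genes of cholesterol synthesis 3 rose, EBP (0.54), DHCR7 (0.41) and IDI1 (0.29), or 4 adjusted over the list alone (median 0.26, adjusted p = 0.000424; adjusted p = 0.315 with an estimated correlation). CD3D, a chain of the T cell receptor complex, rose by 1.54 (adjusted p = 0.000782) and was the 1 of 8 linked T cell markers to do so (list adjusted p = 0.0478; adjusted p = 0.462 with an estimated correlation). CISH, a feedback inhibitor induced by STAT5, rose by 0.63 and was the 1 of 9 linked JAK-STAT genes to pass, or 3 adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.222 with an estimated correlation). The replication genes MCM4 (0.39) and PCNA (0.37) rose, 2 of 12 linked cell cycle genes, or 3 adjusted over the list alone (adjusted p = 0.0318; adjusted p = 0.488 with an estimated correlation). OSM, a cytokine with a receptor on itch neurons, differed by 0.12 (adjusted p = 0.415). IL17A differed by 0.05 (adjusted p = 0.77), IL22 by 0.22 (adjusted p = 0.22), IFNG by 0.01 (adjusted p = 0.953) and IL8 by 0.68 (adjusted p = 0.638), and none of these passed. In the control IL22 read 2.34 to 2.80 and IFNG 2.83 to 3.30. At such dim signals the lack of a call does not show that a gene was unchanged.

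Adipocyte and matrix genes were lower at 24 h. Of 7 linked adipocyte markers 5 fell, or 7 adjusted over the list alone. The median was -0.89 (adjusted p = 0.000158; adjusted p = 0.315 with an estimated correlation). LEP, the adipocyte hormone leptin, fell by 1.65 (SE 0.33, adjusted p = 0.00262), from 7.27 ± 0.77 to 5.63 ± 0.48, in 8 of 8 dogs. LPL, lipoprotein lipase, fell by 1.44, ADIPOQ, adiponectin, by 1.37 and CIDEA, a lipid droplet protein, by 0.89. The other was CFD, adipsin (-0.45), named after its value was seen. Of 7 linked fibroblast and matrix markers 5 fell and 1 rose, also 5 and 1 adjusted over the list alone (median -0.53, adjusted p = 0.0478; adjusted p = 0.315 with an estimated correlation), among them LUM, lumican (-0.91), PDGFRA (-0.77) and COL1A2, a type I collagen chain (-0.55). Other falls were CYP2A13, a cytochrome P450 (-2.11), ABCD2, a peroxisomal fatty acid transporter (-1.52), FMO2, a flavin monooxygenase (-1.42), GLRB, a glycine receptor chain (-1.40), and LMCD1 (-1.34). The muscle markers, whose array mean differed from the control by -0.81, moved the same way as these lists, and 0 of the 8 passed in limma (0 at an unadjusted p under 0.05).

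Over all probe sets, 1272 rose and 2237 fell at 24 h, 114 and 83 of them at least 2-fold, and 9103 had an unadjusted p under 0.05. Among linked genes 382 rose and 759 fell, and the authors' deposited table lists 487 up and 749 down. The share of rises, 36.2%, became 56.9% when each array was centred on its median, and the 24 h array of dog 5 had a median of 4.64 against 4.83 ± 0.08 for the group. The total of 3509 was 2160 without the dog as a block, 2325 without the 9 muscle-rich arrays and 2131 without dog 3, and without the block 15 of 58 named genes lost their call, S100A8 (adjusted p = 0.0750) and IL9 (adjusted p = 0.0534) among them. Without the muscle-rich arrays 16 lost it, and with the actin difference as a covariate 10. Medians of 104.5% and 94.5% of the log2 changes of the named genes were kept under these settings.

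**Figure D3:**
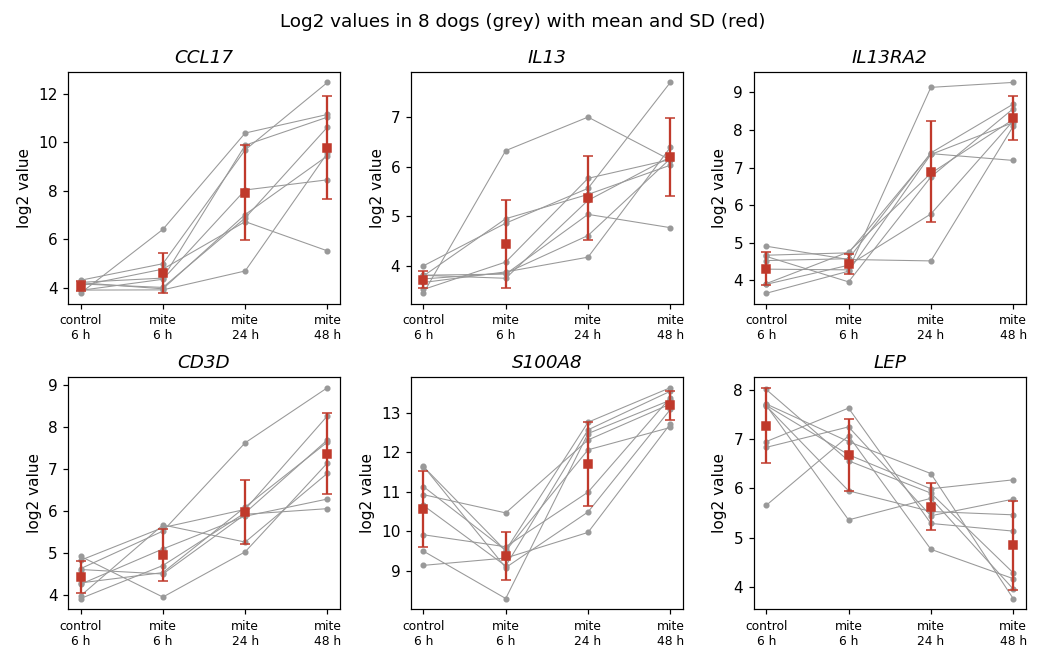
Log2 signal of CCL17, IL13, IL13RA2, CD3D, S100A8 and LEP in each dog in the control and at 6 h, 24 h and 48 h, with the mean and SD of 8 dogs per group. CCL17 goes from 4.06 in the control to 9.77 at 48 h, S100A8 is lower at 6 h (9.37) than in the control (10.57) and higher at 48 h (13.19), and LEP goes from 7.27 to 4.84.

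At 48 h the comparison with control skin asks which transcripts differ at the last biopsy. No lesion score was available at any time. CCL17 rose by 5.71 (SE 0.58, adjusted p = 1.97e-07), to 9.77 ± 2.12, in 8 of 8 dogs. IL13RA2 rose by 4.00 (adjusted p = 5.85e-08), to 8.31 ± 0.59, in 8 of 8 dogs. S100A9, the partner of S100A8 in calprotectin, rose 15.9-fold (log2 3.99, SE 0.48, adjusted p = 1.88e-06), from 8.29 ± 1.13 to 12.27 ± 0.98, in 8 of 8 dogs. CD3D rose by 2.93 (SE 0.27, adjusted p = 8.31e-08), from 4.43 ± 0.37 to 7.36 ± 0.97, in 8 of 8 dogs. LEP fell by 2.43 (SE 0.33, adjusted p = 8.47e-06), to 4.84 ± 0.91, in 8 of 8 dogs.

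Of 22 linked Th2 genes 11 rose and none fell, or 13 and 1 adjusted over the list alone. The median was 0.37 (adjusted p = 6.4e-08; adjusted p = 0.0235 with an estimated correlation). IL9 rose by 3.31, CCL24 by 2.52, IL13 by 2.48 (SE 0.29, adjusted p = 1.42e-06, to 6.19 ± 0.79), IL33 by 1.37 (adjusted p = 0.000183), IL4 by 0.72 (adjusted p = 0.000364) and IL5 by 0.53 (adjusted p = 0.00109), each in 8 of 8 dogs. Of 15 linked dendritic and Langerhans cell markers 13 rose, or 14 adjusted over the list alone. The median was 0.84 (adjusted p = 6.62e-11; adjusted p = 0.0235 with an estimated correlation). Among them were CD209 (2.40), BATF3 (2.28), IDO1 (1.98) and LAMP3, a marker of mature dendritic cells (1.28). The calls of these 2 lists held with an estimated correlation, and those of the other lists described for 48 h did not. CCL5 rose by 2.27 and IL6 by 2.03 (adjusted p = 0.00936, 7 of 8 dogs). GPR171, a receptor found on lymphocytes, rose by 2.95 and CLEC4G, a lectin of sinusoidal endothelium and myeloid cells, by 2.76.

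Of 8 linked T cell markers 5 rose, also 5 adjusted over the list alone: CD3D, CD2 (1.48), CD3G (1.35), CD28 (1.08) and, named after its value was seen, CD247 (0.50) (median 0.79, adjusted p = 2.02e-05; adjusted p = 0.111 with an estimated correlation). Of 9 linked macrophage and monocyte markers 6 rose, also 6 adjusted over the list alone, with AIF1 (1.84), the adaptor TYROBP (1.69), MS4A7 (0.85) and the endotoxin receptor CD14 (0.73) in front (median 0.51, adjusted p = 3.55e-05; adjusted p = 0.0917 with an estimated correlation). Of 11 linked NK and cytotoxic genes 4 rose, or 5 with 1 lower adjusted over the list alone: GZMB (1.29), GZMA (1.13), CTSW (0.86) and KLRB1 (0.78) (adjusted p = 0.00232; adjusted p = 0.111 with an estimated correlation). Of 12 linked cell cycle genes 9 rose, or 10 adjusted over the list alone, with a median of 0.75 (adjusted p = 7.49e-07; adjusted p = 0.111 with an estimated correlation). Cyclin A2, CCNA2, rose by 1.08 (SE 0.17, adjusted p = 4.89e-05), from 6.08 ± 0.24 to 7.16 ± 0.65, and the mitotic genes KIF20A, BUB1B and TTK by 1.05, 1.04 and 0.99. The authors' deposited table also gives CD3E at a fold of 2.3 and TOP2A, a topoisomerase of dividing cells, at 1.8 (adjusted p = 0.013) at 48 h.

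Of 25 linked acute inflammatory genes 13 rose, or 17 adjusted over the list alone, with a median of 0.61 (adjusted p = 6.4e-08; adjusted p = 0.111 with an estimated correlation), led by SAA1 (2.48), CCL19 (2.25), TNFAIP6 (2.14) and IL6. Of 20 linked Th22 and Th17 genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.18, adjusted p = 0.00351; adjusted p = 0.111 with an estimated correlation). The rises were led by S100A9, S100A12 (3.19, adjusted p = 3.16e-05) and S100A8 (2.62, adjusted p = 2.87e-06), and the iron-binding lipocalin LCN2 fell by 0.96. The cytokines that name this axis did not pass against the control: IL17A differed by 0.10 (adjusted p = 0.42) and IL22 by 0.29 (adjusted p = 0.0502). Between allergen biopsies IL22 rose by 0.30 from 6 h to 24 h (limma, adjusted p = 0.0406) and by 0.37 from 6 h to 48 h (adjusted p = 0.0072). For the Th1 cytokine IFNG the difference was 0.02 (adjusted p = 0.876). The control signals of IL22 and IFNG were dim, as given for 24 h, so the lack of a call does not show that they were unchanged. Of 9 linked JAK-STAT genes 4 rose, also 4 adjusted over the list alone, with CISH (0.67), JAK2 (0.60) and SOCS3 (0.34) among them (adjusted p = 0.0057; adjusted p = 0.111 with an estimated correlation). Among 24 linked itch genes HDC, which makes histamine, rose by 0.70, and the list did not shift (median -0.04, adjusted p = 0.801). OSM differed by 0.18 (adjusted p = 0.0954) and IL8 by 1.42 (adjusted p = 0.17). From 6 h to 48 h IL8 rose by 2.15 (limma, adjusted p = 0.0215, 6 of 8 dogs). In the authors' deposited table IL1B has a fold of 1.2 (adjusted p = 0.193) at 48 h. IL31, TSLP and FLG were not analysed here, as that table names none of them.

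Of 7 linked adipocyte markers 6 fell at 48 h, or 7 adjusted over the list alone, with a median of -1.34 (adjusted p = 1.62e-05; adjusted p = 0.144 with an estimated correlation). LEP, LPL (-1.81), ADIPOQ (-1.79, from 12.46 ± 0.48 to 10.67 ± 0.87) and CIDEA (-1.34) showed the largest changes. The muscle markers, lower in 8 of 8 dogs, moved with them. MYH2, a myosin heavy chain of fast muscle fibres, fell by 4.95 (SE 1.75, adjusted p = 0.0465), from 7.63 ± 3.79 to 2.68 ± 0.21, and was the 1 of 8 linked muscle markers to pass, or 0 adjusted over the list alone. The list median was -1.17 (camera, adjusted p = 0.108). Other large falls were CYP2A13 (-2.72), FMO2 (-2.21), ABCD2 (-2.17), FRZB, a secreted Wnt antagonist (-2.06), CLEC3B, tetranectin (-1.97), and CRYAB, a small heat shock protein abundant in muscle (-1.86), each in 8 of 8 dogs. Of 10 linked melanocyte markers 3 fell, or 5 adjusted over the list alone: the pigment enzymes TYR (-1.13) and DCT (-0.93) and the melanosome protein MLANA (-1.10), each in 6 of 8 dogs (median -0.49, adjusted p = 0.0363; adjusted p = 0.451 with an estimated correlation). Of 15 linked keratinocyte activation genes 4 rose and 6 fell, or 4 and 7 adjusted over the list alone, without a shift of the list (adjusted p = 0.267). TIMP1, an inhibitor of matrix proteases, rose by 1.83, and the matrix glycoprotein TNC fell by 1.20, the serpin SERPINB2 by 1.10 and MMP3 by 1.08. Of 14 linked genes of the cornified envelope and differentiation 0 passed in limma at 6 h, 24 h or 48 h (2, 1 and 1 at an unadjusted p under 0.05, with list adjusted p = 0.141, 0.143 and 0.595).

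Over all probe sets, 4541 rose and 3897 fell at 48 h, 469 and 225 of them at least 2-fold, and 13224 had an unadjusted p under 0.05. Among linked genes 1288 rose and 1150 fell, and the authors' deposited table lists 2138 up and 1407 down. The total of 8438 was 5448 with the actin difference as a covariate, and IL6 then lost its call (adjusted p = 0.0827), as it did with the muscle score as a covariate (adjusted p = 0.0588). Of 106 named genes 32 lost their call with the actin difference, 18 without the dog as a block and 16 with the muscle score.

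**Figure D4:**
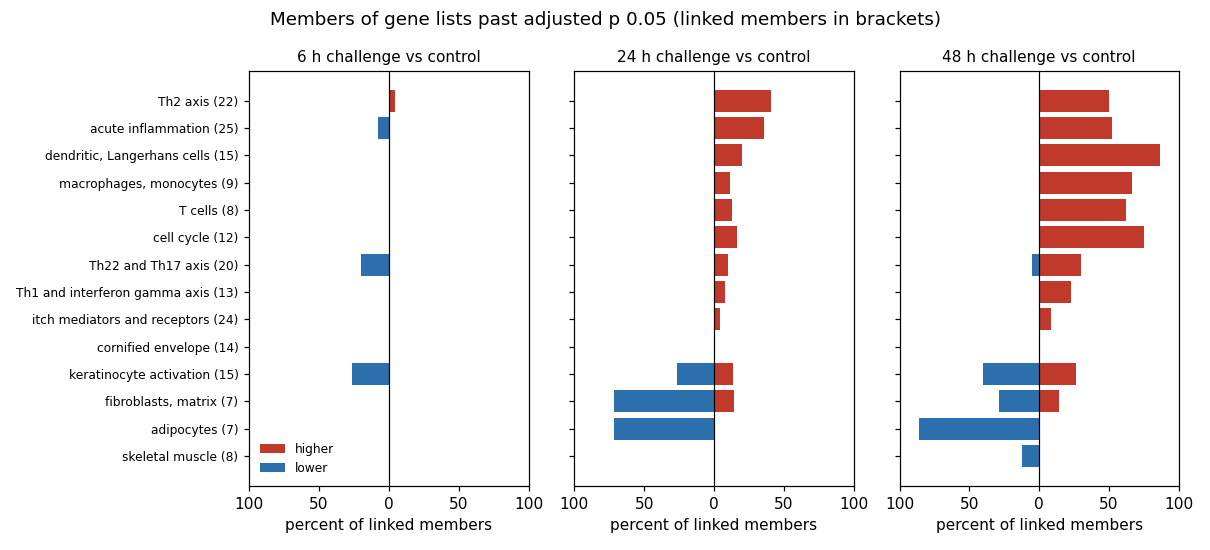
Percent of the linked members of 14 gene lists that rose or fell past an adjusted p of 0.05 at 6 h, 24 h and 48 h against the control. For dendritic and Langerhans cell markers 3 of 15 linked members rose at 24 h and 13 of 15 at 48 h, while adipocyte markers show falls at 24 h and 48 h.

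The changes at 24 h and 48 h overlapped. Of the probe sets called at both times, 1106 rose and 1793 fell, and 0 moved in opposite directions. These counts share the control arrays. In a split by dogs, each time was fitted on its own 4 dogs, for allergen and control arrays alike. There 103 and 32 rises and 194 and 64 falls were shared. Each fit then held fewer arrays, so the drop does not measure the effect of the shared controls alone. Across probe sets, which are not independent replicates, the changes at the 2 times correlated with r = 0.84 (jackknife SE 0.067), and simulated data with the same shared control arrays and no true change gave 0.50. With the dogs split r was 0.60 and 0.74. The 6 h and 24 h lists shared 14 rises and 367 falls, with 17 called in opposite directions, and with the dogs split 0 and 0 rises and 10 and 0 falls (limma). Their r was 0.004 (jackknife SE 0.142), below the 0.50 that the shared controls alone gave in simulated data. The 6 h and 48 h lists shared 26 rises and 393 falls, with 93 in opposite directions, and with the dogs split 0 and 0 rises and 47 and 0 falls (limma). Their r was -0.16 (jackknife SE 0.117), also below the simulated 0.50. The simulated noise was independent between probe sets, so 0.50 leaves out differences shared by many probe sets, such as muscle. The muscle mean was above the control at 6 h (1.29) and below it at 24 h (-0.81) and 48 h (-1.81). Whether muscle moved these correlations and overlaps was not tested.

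Between 6 h and 24 h, both after allergen, acute inflammatory genes showed the clearest rise: 15 of 25 linked members rose, or 17 adjusted over the list alone, with a median of 0.95 (adjusted p = 2.62e-12; adjusted p = 0.104 with an estimated correlation). SAA1 rose by 2.95 (SE 0.34, adjusted p = 1.04e-05), from 8.52 ± 1.08 to 11.47 ± 0.61, CCL19 by 2.25, IL6 by 2.23 and TNFAIP6 by 2.22, each in 8 of 8 dogs. CCL17 rose by 3.31, S100A9 by 2.93, from 6.90 ± 0.98 to 9.83 ± 1.68, and S100A12 by 2.90. Among 24 linked itch genes OSMR, the receptor chain shared by oncostatin M and IL31 (1.11, adjusted p = 0.000812, 8 of 8 dogs), and HDC (0.43) rose, and NPR1 fell by 0.33. Of 8 cholesterol synthesis genes 5 rose, or 6 adjusted over the list alone, EBP (0.88), SQLE (0.74), DHCR7 (0.45), IDI1 (0.42) and, named after its value was seen, their regulator SREBF2 (0.33) (adjusted p = 4.11e-06; adjusted p = 0.119 with an estimated correlation). Of 13 immediate early and heat shock genes 4 rose, or 8 adjusted over the list alone: DUSP1 (0.66), HSPA8 (0.62), IER3 (0.58) and EGR2 (0.49) (adjusted p = 0.00041; adjusted p = 0.119 with an estimated correlation). Of 22 linked Th2 genes 9 rose, or 10 adjusted over the list alone (adjusted p = 0.000839; adjusted p = 0.119 with an estimated correlation), among them the matrix protein POSTN, periostin (1.12). Of 11 linked neutrophil markers 5 rose, also 5 adjusted over the list alone: S100A9, S100A12, S100A8 (2.33), FCGR1A (1.44) and, named after its value was seen, TREM1 (0.85) (adjusted p = 0.0039; adjusted p = 0.119 with an estimated correlation).

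Falls from 6 h to 24 h included 6 of 7 adipocyte markers, or 7 adjusted over the list alone (median -0.80, adjusted p = 0.000839; adjusted p = 0.343 with an estimated correlation), and 5 of 7 fibroblast and matrix markers, also 5 adjusted over the list alone, LUM (-1.24), COL1A2 (-0.85), DCN (-0.56), PDGFRA (-0.56) and, named after its value was seen, LOX (-0.41) (adjusted p = 0.00191; adjusted p = 0.119 with an estimated correlation). CYP2A13 fell by 2.90, FMO2 by 2.09, CLEC3B by 1.82 and SEPP1, the plasma selenoprotein, by 1.77, each in 8 of 8 dogs. The muscle list had a median change of -1.89 (adjusted p = 0.0207; adjusted p = 0.611 with an estimated correlation), with 0 of 8 members past the test in limma (7 at an unadjusted p under 0.05) and 6 lower adjusted over the list alone. In all, 3621 probe sets rose and 3795 fell, with 13479 at an unadjusted p under 0.05, and the share of rises, 48.8%, became 68.3% with arrays centred on their medians. The total of 7416 was 4378 without dog 3, 4696 when the fit used these 2 groups alone, 3411 with the muscle score as a covariate, 487 with the actin difference as a covariate and 0 without the 9 muscle-rich arrays (limma, 4835 at an unadjusted p under 0.05). Of 81 named genes called, 70 lost their call with the actin difference, which went from 2.78 at 6 h to 2.08 at 24 h, and 81 lost it without the muscle-rich arrays. Medians of 76.7% and 78.6% of their log2 changes were kept. Without the muscle-rich arrays only dogs 7 and 8 kept both a 6 h and a 24 h array.

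From 24 h to 48 h, members of immune cell and cell cycle lists rose, many of which had not passed at 24 h against the control. Of 15 dendritic and Langerhans cell markers 6 rose, or 10 adjusted over the list alone (median 0.57, adjusted p = 1.63e-10; adjusted p = 0.0551 with an estimated correlation), with CD209 up by 1.37 (SE 0.24, adjusted p = 0.00369), from 5.80 ± 0.77 to 7.16 ± 0.79. Of 12 cell cycle genes 7 rose, or 10 adjusted over the list alone (median 0.52, adjusted p = 4.86e-09; adjusted p = 0.0826 with an estimated correlation). Of 8 T cell markers 4 rose, or 7 adjusted over the list alone, CD3D (1.39, adjusted p = 0.00677), CD2 (0.97), CD3G (0.86) and CD247 (0.40) (median 0.52, adjusted p = 6.97e-07; adjusted p = 0.0826 with an estimated correlation). Of 9 macrophage markers 3 rose, or 7 adjusted over the list alone (adjusted p = 3.39e-06; adjusted p = 0.0566 with an estimated correlation), MS4A7 (1.11), AIF1 (0.99) and TYROBP (0.99). The largest rises were S100A9 (2.45), S100A12 (2.10), CLEC4G (1.72) and EMR4P, a receptor-like gene of myeloid cells (1.72), each in 8 of 8 dogs. IL13RA2 (1.42) and POSTN (1.12) were the 2 of 22 Th2 genes that rose, or 6 adjusted over the list alone (adjusted p = 0.00102; adjusted p = 0.0966 with an estimated correlation). Falls were few, and among them were the activin antagonist FST (-0.57), BEX4 (-0.46) and MC5R, a melanocortin receptor of sebaceous glands (-0.44). Of 17 linked hair follicle genes 0 passed in limma (6 at an unadjusted p under 0.05), with a list median of -0.18 (adjusted p = 3.81e-05; adjusted p = 0.358 with an estimated correlation). In all, 1017 probe sets rose and 79 fell, and 5966 had an unadjusted p under 0.05. The total of 1096 was 463 without the dog as a block, 433 with these 2 groups alone, 314 with the actin difference as a covariate and 207 without the 9 muscle-rich arrays. It was 492 without dog 1, 461 without dog 2, 270 without dog 4, 247 without dog 5 and 553 without dog 8. Of 32 named genes 25 lost their call without the muscle-rich arrays, 24 with the actin difference and 17 without the block. Medians of 96.4% without the muscle-rich arrays and 86.6% with the actin difference were kept of the log2 changes of the named genes.

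Across the whole interval from 6 h to 48 h, S100A9 rose 41.5-fold (log2 5.37, SE 0.48, adjusted p = 3.94e-08), CCL17 by a log2 of 5.18, S100A12 by 5.00 and IL13RA2 by 3.87, each in 8 of 8 dogs. Of 15 dendritic and Langerhans cell markers 13 rose, also 13 adjusted over the list alone (adjusted p = 5.61e-09; adjusted p = 0.0869 with an estimated correlation), as did 17 of 25 acute inflammatory genes, or 19 with 1 lower adjusted over the list alone (median 1.08, adjusted p = 3.81e-09; adjusted p = 0.101 with an estimated correlation). The muscle genes MYH2 (-7.09, SE 1.75, adjusted p = 0.00322), MYLPF (-5.88), TNNC2 (-5.70) and CSRP3 (-5.38) fell in 8 of 8 dogs, and 6 of 8 linked muscle markers fell, or 7 adjusted over the list alone (median -2.46, adjusted p = 0.00181; adjusted p = 0.36 with an estimated correlation). In all, 6774 probe sets rose and 5829 fell, with 16930 at an unadjusted p under 0.05, the largest total of the 6 comparisons. That total of 12603 was 6084 with the muscle score as a covariate, 1604 without the 9 muscle-rich arrays and 850 with the actin difference as a covariate, which left 14 of 105 named genes past the test.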

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

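The tests with the actin covariate, with the muscle covariate and without the 9 muscle-rich arrays use settings chosen only after the data were seen, and the bounds of each covariate test were written before its result.

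Some arrays lay far from the other 7 of their group. For 164 genes in 4 groups, the gap between the highest or lowest array and its neighbour, divided by the range of the group, was above the 95% critical value of Dixon's test in 50 of 656 groups. Chance flags about 1 in 20 groups, or 32.8 here. Ratio and dog are given for each. In the control group the highest array stood apart for CRYAB (0.565, dog 7), DCN (0.765, dog 1), DUSP1 (0.587, dog 1) and MMP3 (0.613, dog 1). The lowest stood apart for CXCL12 (0.544, dog 8), FOSL1 (0.605, dog 4), HSPH1 (0.543, dog 4), IFNG (0.666, dog 1) and IL22 (0.605, dog 7). At 6 h the highest array stood apart for CCL17 (0.567, dog 2), CLEC3B (0.570, dog 6), DCN (0.547, dog 6), GBP5 (0.723, dog 2), IL13 (0.534, dog 7), IL33 (0.716, dog 6), IL4 (0.566, dog 2), LUM (0.592, dog 6) and VWF (0.573, dog 6). The lowest stood apart for BUB1B (0.529, dog 6), IL36G (0.650, dog 1), IL9 (0.603, dog 8), KIF20A (0.543, dog 6), OCLN (0.691, dog 6) and SREBF2 (0.553, dog 6). At 24 h the highest array stood apart for ADM (0.678, dog 4), CD3D (0.589, dog 6), CISH (0.593, dog 5), CYP1A1 (0.683, dog 8), KLRB1 (0.576, dog 6), MMP3 (0.689, dog 1) and MZB1 (0.539, dog 6). The lowest stood apart for CTSW (0.591, dog 5), ERRFI1 (0.626, dog 6), GLRB (0.571, dog 3), IL5 (0.541, dog 8) and XCL1 (0.552, dog 5). At 48 h the highest array stood apart for CD14 (0.607, dog 1), GLRB (0.557, dog 8), HDC (0.631, dog 6), MC5R (0.593, dog 7), MMP3 (0.567, dog 2) and SLC12A2 (0.566, dog 1). The lowest stood apart for CLDN1 (0.642, dog 6), CTNNB1 (0.644, dog 6), FOSL1 (0.536, dog 1), ITGA2 (0.589, dog 3), KRT28 (0.539, dog 6), PER1 (0.613, dog 5), TIMP1 (0.533, dog 7) and TTK (0.584, dog 3). Dog 6 accounts for 17 of the 50, and 9 of these are on its 6 h array, which has the highest muscle mean of its group (8.41) and a mean correlation of 0.964 with the other arrays. The median signal of the 24 h array of dog 5, 4.64, was also apart from its group (0.820). No explanation was tested for these.

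Among the 164 genes checked, 5 had changes against the control of opposite sign at 6 h and later, both past the test. They fell at 6 h and rose later. Because they were picked for this, the differences between times follow from the choice and are given as values only: 2.25 at 24 h and 3.09 at 48 h for CCL19, 2.33 and 3.82 for S100A8, and at 48 h 5.00 for S100A12, 1.37 for IL36G and 1.30 for SOD2.

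Of the 1239 probe sets past the test at 6 h 1121 fell, with a median change of -0.44, and muscle RNA as the whole cause is argued against, since 93.6% of that median was kept with the muscle covariate (-0.41, median SE 0.104 before and 0.107 after), and 530 probe sets then passed. Without the 9 muscle-rich arrays the median was -0.36, but 0 passed in limma (1835 at an unadjusted p under 0.05). That fit had 3 arrays left at 6 h and an SE of 0.170. Only dog 8 kept both its control and its 6 h array, so the setting can hardly test muscle within dogs. Muscle as part of the cause stays open: 60.04% of these probe sets had a negative slope on the muscle score in the other groups (53.0% of all probe sets), and with dog 4 swapped 1368 passed at a muscle difference of 2.26 against 1.29. With the actin covariate the change shrank to 70.6% (-0.31), its SE grew to 0.126 and 0 passed in limma (4007 at an unadjusted p under 0.05). Lower RNA integrity and an early response to the allergen cannot be told apart for these probe sets, since the actin difference moves with the group itself. The GAPDH control did not show a wider 3' minus 5' gap at 6 h (5' signal higher by 0.82, 3' by 0.47). Its 5' signal moved with muscle, at 11.67 to 12.77 on the 9 muscle-rich arrays and 10.06 to 11.62 on the others. The GAPDH gap therefore cannot decide on integrity, and lower integrity rests on actin alone.

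Adipocyte markers fell at 48 h, with a list median of -1.34 whose call is lost with an estimated correlation (adjusted p = 0.144). Less muscle in the 48 h biopsies, taken as a sign of less subcutaneous tissue, is argued against as the whole cause, since 105% of that median was kept with the muscle covariate (-1.41). The score measures muscle and not fat, and the 48 h arrays all read 2.96 to 3.19 on it. It therefore does not test the amount of subcutaneous tissue as such. With the actin covariate the list median was -1.23, and 5 of 7 members passed, against 6 without it. Biopsies that held less fat but the same muscle were not tested and stay open, as does an effect of the allergen on adipocytes, which may be the source of the fall.

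Dendritic and Langerhans cell markers rose at 48 h, with a list median of 0.84. Less muscle in the 48 h biopsies, which would raise all other genes alike, is argued against as the whole cause, since 88.9% of that median was kept with the muscle covariate (0.75). With the actin covariate the list median was 0.70 (adjusted p = 1.54e-08; 3.39e-11 to 0.0235 over the 10 settings run for this list), and 12 of 15 members passed, against 13 without it. Of the 106 named genes called at 48 h 74 kept their call with that covariate and 32 lost it, with a median of 87.3% of the log2 change kept. A larger share of immune cells in the skin may explain the rise, and the share of each cell type was not measured.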

How the results depend on the processing

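The tests with the muscle covariate, the actin covariate, without the 9 muscle-rich arrays, without the 24 h array of dog 5 and with an ordinary linear model were chosen only after the data were seen. Where no cause is given below, the cause was not tested.

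The dog as a block, which follows the pairing of the biopsies, changed the totals. Without it 469 probe sets passed at 6 h (1239 with it), 2160 at 24 h (3509) and 463 from 24 h to 48 h (1096), and the other 3 totals stayed within 1.5 times. Of the probe sets called with the block, 469 of 1239, 2149 of 3509, 6440 of 8438, 5354 of 7416, 463 of 1096 and 10469 of 12603 were also called without it (6 h, 24 h, 48 h, 6 h to 24 h, 24 h to 48 h, 6 h to 48 h). Of 222 list results 214 kept their side of the threshold. An ordinary linear model without the block gave 331, 1942 and 226 for the same 3 comparisons. With the dog as a random effect all 6 totals stayed within 1.5 times.

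Quantile normalization, centring, an intensity trend with a robust prior, and leaving out the dimmer 50% of probe sets each kept all 6 totals within 1.5 times. Of 222 list results, 214 under quantile normalization and 216 under centring kept their side of the threshold, and 156 did so with an estimated correlation, under which 66 calls were lost. A fold of at least 1.5, which only removes calls, left 236 at 6 h, 845 at 24 h, 2234 at 48 h, 1456 from 6 h to 24 h, 470 from 24 h to 48 h and 3273 from 6 h to 48 h. Fits to 2 groups only, with fewer arrays for the spread, gave 4696 from 6 h to 24 h and 433 from 24 h to 48 h. Array weights gave 2004 at 6 h. With each time fitted on separate dogs, the correlation of changes for 6 h and 24 h was -0.24 with dogs 1 to 4 at 6 h and 0.11 with dogs 5 to 8. For 24 h and 48 h it was 0.60 and 0.74. Leaving out each dog gave 283 to 1878 at 6 h, 2131 to 3278 at 24 h, 6758 to 7940 at 48 h, 4378 to 7618 from 6 h to 24 h, 247 to 1627 from 24 h to 48 h and 9610 to 12153 from 6 h to 48 h.

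With the muscle covariate 530 passed at 6 h, 3411 from 6 h to 24 h and 6084 from 6 h to 48 h. The score is built from muscle genes, and it removed the shift of the muscle list from 6 h to 24 h (median -0.00058, camera, adjusted p = 0.749). From 6 h to 48 h the score turned the sign of CSRP3 (1.02), MYBPC1 (0.10), MYLPF (0.049), PYGM (0.12) and TNNC2 (0.019), none of them past the test. Without the 9 muscle-rich arrays, with fewer arrays, 0 passed in limma at 6 h (1835 at an unadjusted p under 0.05), 2325 at 24 h, 0 from 6 h to 24 h (4835), 207 from 24 h to 48 h and 1604 from 6 h to 48 h. In that fit only dog 8 kept both arrays of the 6 h comparison, and only dogs 7 and 8 those of 6 h to 24 h. The muscle list at 6 h was at -0.32, and from 6 h to 48 h LUM was at 0.023 and PYGM at 0.089. With the actin covariate 0 passed at 6 h in limma (4007), 5448 at 48 h, 487 from 6 h to 24 h, 314 from 24 h to 48 h and 850 from 6 h to 48 h. It reversed, from 6 h to 48 h, the hair follicle list (0.13), BANK1 (-0.15), ELOVL7 (-0.27), KRT28 (0.13) and LGR5 (0.056). Without the 24 h array of dog 5, 1915 passed at 6 h and 636 from 24 h to 48 h.

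The alternative that averages probe sets of the same gene was not run, since the link names 1 probe set per gene. Median signals of the arrays span 4.64 to 4.91, and no background level was given to set them against.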

Other observations

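The comparison of split totals with the muscle difference was chosen only after the data were seen, as were the named members STS and FPR2 at 48 h.

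Further gene lists describe smaller groups of genes at 48 h. Of 7 linked mast cell markers 2 rose and 1 fell, also 2 and 1 adjusted over the list alone: the carboxypeptidase CPA3 rose by 1.38 (adjusted p = 0.000135, 8 of 8 dogs) and HDC by 0.70, and the receptor KIT fell by 0.38 (list adjusted p = 0.735). Of 12 linked genes of T cell activation 3 rose, or 6 adjusted over the list alone, CD69 (1.30), PDCD1LG2 (0.83) and IL2 (0.47) (adjusted p = 0.0262; adjusted p = 0.172 with an estimated correlation). Of 9 linked B and plasma cell markers 3 rose, or 4 adjusted over the list alone: IGJ (1.25), MZB1 (1.17) and MS4A1 (0.23) (adjusted p = 0.0363; adjusted p = 0.123 with an estimated correlation). Of 11 linked neutrophil markers 4 rose and 1 fell, or 4 and 2 adjusted over the list alone: S100A9, S100A12, S100A8, FCGR1A (1.75) and FPR2 (-0.24) (adjusted p = 0.0169; adjusted p = 0.111 with an estimated correlation). The 3 S100 genes are also in the Th22 and Th17 list. ALOX15 (0.32) was the 1 of 3 linked eosinophil markers to rise (list adjusted p = 0.335). Of 12 linked genes of the type I interferon response 2 rose, or 3 adjusted over the list alone, MX2 (0.87) and IFIH1 (0.54) (adjusted p = 0.00909; adjusted p = 0.318 with an estimated correlation). Of 13 linked Th1 genes 3 rose, or 4 with 1 lower adjusted over the list alone, with GBP5 (1.19) and XCL1 (0.90) among them (list adjusted p = 0.071).

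Lists of structure and metabolism were also tested at 48 h. Of 24 linked genes of ceramide and barrier lipid synthesis 2 rose and 3 fell, or 2 and 4 adjusted over the list alone: CERS2 (0.44), SMPD1 (0.19), SCD (-1.10), ELOVL6 (-0.92) and STS (-0.18) (list adjusted p = 0.656), and at 6 h ABCA12 fell by 0.53 (adjusted p = 0.0403). Of 13 junction genes 3 fell, or 3 with 1 higher adjusted over the list alone, CLDN1 (-0.50), OCLN (-0.40) and CLDN12 (-0.30) (list adjusted p = 0.293). Of 8 cholesterol synthesis genes 2 rose, also 2 adjusted over the list alone, EBP (0.51) and DHCR7 (0.35) (adjusted p = 0.0331; adjusted p = 0.451 with an estimated correlation). Among 7 fibroblast and matrix markers COL6A1 rose by 0.75, LOX fell by 0.77 and DCN fell by 0.31, or 2 rises and 3 falls adjusted over the list alone (list adjusted p = 0.586). Among 5 endothelial markers VWF rose by 0.45 and PECAM1 fell by 0.85 (list adjusted p = 0.586). Among 9 sebaceous gland markers KRT79 (0.99) and FAR2 (0.46) rose, and CIDEA fell by 1.34 and MC5R fell by 0.56 (list adjusted p = 0.735). SLC12A2 (-1.03) was the 1 of 4 sweat gland markers to fall (list adjusted p = 0.656). Of 7 glucocorticoid responsive genes 4 fell, ZBTB16 (-0.83), KLF9 (-0.52), PER1 (-0.38) and ERRFI1 (-0.32), or 5 with 1 higher adjusted over the list alone (list adjusted p = 0.125). Among immediate early and heat shock genes IER3 rose by 0.51, HSPH1 fell by 0.89 and FOSL1 fell by 0.35, or 2 rises and 3 falls adjusted over the list alone (list adjusted p = 0.874). Among 6 glycolysis and hypoxia genes PGAM1 (0.35) and CA9 (0.39) rose and ADM fell by 0.73, or 2 rises and 3 falls adjusted over the list alone (list adjusted p = 0.99), and GUSB (0.36) was the 1 of 3 housekeeping genes to rise (list adjusted p = 0.284). Of 17 hair follicle, 7 nerve and Schwann cell and 6 blood and platelet genes, 0 passed in limma at 48 h (5, 1 and 1 at an unadjusted p under 0.05), with list adjusted p = 0.057, 0.931 and 0.586.

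One hypothesis was that the 6 h biopsies were taken at another time of day than those at 24 h and 48 h, which could move circadian clock genes. Of 9 linked clock genes 1, DBP (-0.29), passed from 6 h to 24 h. From 24 h to 48 h 0 passed in limma (2 at an unadjusted p under 0.05). The median absolute change was 0.11 from 24 h to 48 h and 0.16 from 6 h to 24 h, a ratio of 0.697, and over all linked genes the medians were 0.08 and 0.12. The control was taken at 6 h too, and at 24 h against the control 1 passed, PER3 (-0.21, adjusted p = 0.0391, 8 of 8 dogs). Fewer than 2 clock genes passed from 6 h to 24 h, the bound set in advance against time of day. Only 9 of the 18 clock genes of the list were linked, and a count of calls misses smaller shifts. The count therefore cannot decide the question, and time of day is not excluded. PER1 was the 1 clock gene that fell at 48 h, or 3 adjusted over the list alone (list adjusted p = 0.111).

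Totals were also counted with the 2 groups swapped within some dogs, in 100 of the 128 possible splits. At 24 h 1 of 100, the real one, gave as many (3509; highest other 1004), at 48 h 1 (8438; 5064), from 6 h to 24 h 1 (7416; 4706) and from 6 h to 48 h 1 (12603; 8864). Chance alone is unlikely for these, at 1 of 100 each and not adjusted over the comparisons. At 6 h 2 of 100 gave as many, the real split (1239) and one with dog 4 swapped (1368). From 24 h to 48 h 2 did, the real split (1096) and one with dog 7 swapped (1388). Chance alone is less likely there too, at 2 of 100, but it is not excluded. A swap of 1 dog gave more calls than the real split, which may come from a structure of the samples beyond the groups. At 6 h the swap of dog 4 also raised the difference in muscle mean from 1.29 to 2.26, and whether muscle is part of that structure stays open (Spearman 0.22 between totals and the size of the muscle difference over the splits). From 24 h to 48 h the swap of dog 7 moved it by little, to -0.99.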
